A study of Synechocystis sp. PCC 6803 with 4 samples.

How the data were processed

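Total RNA of 4 Synechocystis samples was measured, 2 of an ethylene-producing strain and 2 of the wild type, all taken 4 h after addition of 1 mM IPTG, per the labels' protocols. RNA was labelled with Cy3 directly, without a reverse transcription step, per the labels' protocols, so a probe reports the strand it is complementary to. Groups and replicate numbers come from the sample labels.

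The spot intensity values were made with Agilent Feature Extraction 10.7.3.1 from 1-colour scans, per the file headers. The processed signal is the intensity after subtraction of a fitted background surface and multiplicative detrending, per the file headers, and is not normalized between arrays. The table of values that the authors deposited for the same arrays is on a log2 scale, and the submitters' processing notes name limma with no version. Its rows matched the spots by feature number. Each column correlated with log2 processed signal of its own array at 0.979 to 0.982, and the column medians over non-control spots were 10.94, 10.94, 10.96 and 10.95. It was not centred per gene; the exact steps are not given in the sources used here, and normexp with an offset of 50 on median signals followed by cyclic loess came within a median absolute difference of 0.0114. Negative control spots had a median signal of 1478 to 1768 units against a local background of 26.5 to 29, so subtracting the local background does not remove their signal.

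The main values were log2 processed signal minus each array's 75th percentile over the 40886 non-control spots of 42303. Spots with an outlier flag were left out, and 50 of 20363 probes without a usable spot on every array were dropped. Spots of a probe were averaged, then probes of a feature, which left 8802 features. Features were kept for testing where at least 1 probe was well above background, on at least 50% of its spots, on both arrays of a group; 7939 remained, 3278 of them genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior degrees of freedom 3.81, residual degrees of freedom 2), two-sided, with Benjamini-Hochberg adjustment over all 7939 features and a threshold of 0.05. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so significance rests on the spread pooled across features. For a feature with no probe well above background on any array of a group, a bound is given: the bright group's mean against the mean over the dim arrays of the higher of the feature's own value and the lowest signal of a probe well above background on that array. No such bound was used for ranking. In all, 733 features share a probe sequence with a feature of another name, among them 25 called genes, 7 of which share one with another gene.

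Gene lists were fixed before the data were examined: ethylene locus, major and core pili, minor pilins, chemotaxis-like phototaxis, photoreceptors and cAMP, photosystem I, photosystem II, phycobilisome, cytochrome b6f and carriers, ATP synthase, NDH-1 and respiration, low-carbon inducible, carboxysome and Rubisco, nitrogen assimilation, arginine metabolism, central carbon, chaperones and proteases, high light and oxidative stress, iron, phycobilisome degradation, ribosomal proteins, regulatory RNAs, and plasmids pSYSM, pSYSX, pSYSA and pSYSG by tag number. The 21 lists with at least 3 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, and with an estimated correlation and fry as alternatives. The files name genes by locus tag only. The reference table used here (assembly ASM28445v1) names genes by other tags and 0 of the 3364 gene names matched it, so symbols and functions are background knowledge, and no coordinates are given. The non-coding kinds were read from the names of features.

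Genes named were fixed by rule before the data were examined: the 15 largest rises and 15 largest falls among genes past the threshold whose arrays do not overlap between groups, every ethylene locus gene, up to 4 members of each list with the smallest p, and the 5 smallest p in each direction among non-coding features. Genes named outside this rule are said to be so. Alternatives, also fixed beforehand, were median centring, quantile normalization, normexp background correction with an offset of 50 followed by the 75th percentile or quantile normalization, the authors' deposited value table, no filter on dim features, a filter on all 4 arrays, the median over probes, an intensity trend in the variance prior, the replicate number as a block, adjusted p under 0.1 and 0.01, and leaving out each array in turn. With 1 array left in a group, it was assumed to vary like the other group.

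The test was tested on simulated data: 7939 features were drawn with the real means and the fitted prior, and 200 of them were changed. It recovered 1 of 50 features changed by 0.5 on the log2 scale, 39 of 50 changed by 1, 47 of 50 changed by 2 and 50 of 50 changed by 3, with 10 calls among features left as they were. The simulated spreads followed the prior that the test itself assumes, which favours the test. Against that, only 147 features were called there and 497 in the data, so the adjusted threshold was stricter in the simulation. These counts thus do not give the share of real changes recovered.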

Results

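Total RNA from the cyanobacterium Synechocystis was hybridised to 4 single-colour Agilent arrays, 2 from a strain carrying an inducible gene for the ethylene-forming enzyme and 2 from the wild type. This enzyme, known from bacteria, makes ethylene from 2-oxoglutarate and arginine. All cultures had received 1 mM IPTG, the inducer, 4 h before RNA extraction. Each array held 40886 spots of 20363 probes, of which between 83.3% and 86.8% were well above background, and no spot was saturated. The 75th percentile of processed signal lay between 4057 and 4739 scanner units. Correlation across features was 0.994 within the ethylene-producing strain, 0.993 within the wild type and 0.969 to 0.980 between them. Genes are named by the locus tags of the array design, and what each is known to do is given as background. The number of arrays limits the precision of every value, and as nothing says that the arrays came from separate cultures, the p-values measure only the spread between these samples.

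The comparison asked which transcripts differ in a strain that makes ethylene, in a series concerned with ethylene and phototactic movement. The ethylene-producing strain had much lower slr1214, a response regulator gene beside the ethylene receptor gene. It had higher transcripts of the alkaline phosphatase gene sll0654, the phosphate-binding protein gene sll0680 and the adjacent genes sll1077 to sll1081. Part of the plasmid pSYSA was lower, as were many features named as spacers and isiA (sll0247), a chlorophyll-binding protein gene of the iron starvation response. Of 3278 protein-coding genes tested, 90 were higher and 98 lower in the ethylene-producing strain at an adjusted p under 0.05 (limma, Benjamini-Hochberg over 7939 features), and 63 of these 188 changed at least 2-fold, 29 up and 34 down. The 2 arrays of each group did not overlap for 1999 genes, or 61.0%, where chance gives 33.3%. With normexp background correction the split was 174 higher and 114 lower, and in the authors' value table it was 92 higher and 153 lower.

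Among the ethylene locus genes, 1 of 3 changed, and the count was also 1 when adjusted over the list alone. slr1214, which encodes a response regulator, fell 10.9-fold, from a log2 signal of -0.45 ± 0.30 (SD, n = 2) to -3.91 ± 0.29 relative to each array's 75th percentile (log2 fold change -3.45 ± 0.20 SE, limma adjusted p = 5.07e-04). slr1212, the ethylene and ultraviolet light receptor gene, did not pass the test (0.24 ± 0.11 SE), nor did the response regulator gene slr1213 (0.05 ± 0.14 SE, a value whose sign turned with median centring). The list's mean was -1.05 and its median 0.05, and it was not called as a group (camera adjusted p = 0.404). The transcript of the introduced enzyme was not analysed here, since no probe is named for it.

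Few of the motility genes fixed beforehand passed. Of 16 chemotaxis-like phototaxis genes, 3 rose, all from the tax2 cluster: sll1294 (log2 fold change 0.72 ± 0.12 SE), sll1292 (0.65 ± 0.10 SE) and sll1291 (0.61 ± 0.10 SE). Their neighbour sll1293 gave 0.54 ± 0.12 SE (limma adjusted p = 0.0593), and 4 of the 16 rose when adjusted over the list alone. Each of these 3 calls ended when any 1 array was left out, that of sll1294 also with the median over probes (0.67, limma adjusted p = 0.0527). The list's median was -0.02, its mean 0.12, and camera called no shift (adjusted p = 0.549). None of the 13 major and core pilus genes passed by either adjustment; the major pilin gene pilA1 (sll1694) had a log2 fold change of 0.41 ± 0.17 SE. The list's median was -0.02 and its mean 0.02. None of 9 minor pilin genes passed over all features, while 1 was higher and 4 were lower when adjusted over the list alone. The lowest p-values there belonged to slr1929 (-0.67 ± 0.15 SE), slr1930 (-0.38 ± 0.10 SE), slr1931 (-0.40 ± 0.11 SE) and slr1928 (-0.63 ± 0.19 SE), and the list was not called (camera adjusted p = 0.295). Of 10 photoreceptor and cAMP signalling genes none passed, and 1 was lower when adjusted over the list alone, slr1693, a partner of the blue light receptor PixD (-0.48 ± 0.10 SE).

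**Figure D1:**
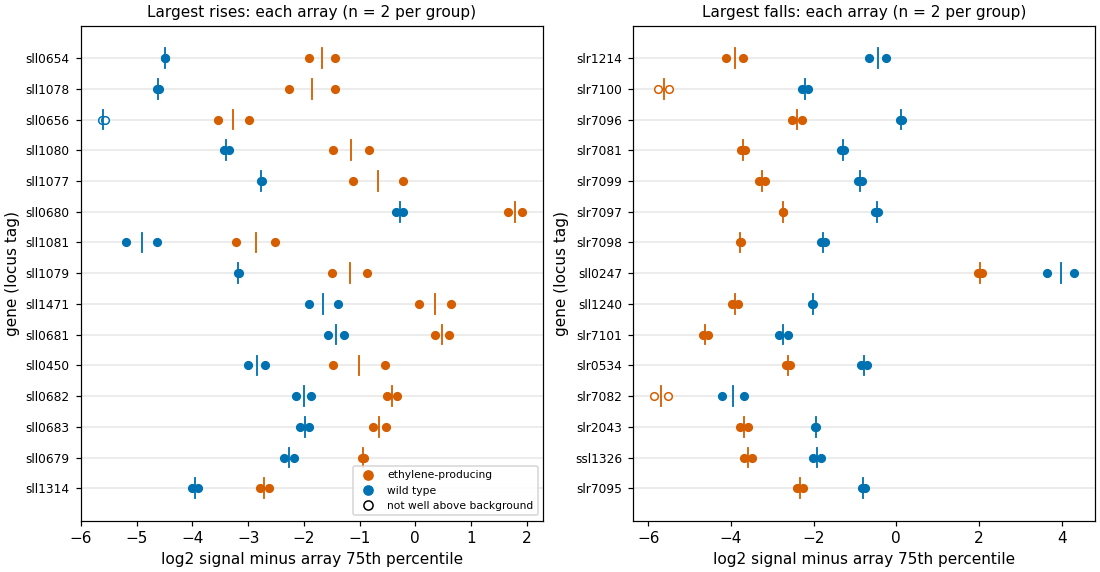
Signal of the 15 largest rises and the 15 largest falls on each array, as log2 processed signal minus the array's 75th percentile (x axis), by locus tag (y axis). Filled points are single arrays (orange ethylene-producing, blue wild type, n = 2 each), vertical bars are group means and open points are genes not well above background in that group; slr1214 drops from a mean of -0.45 to -3.91.

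The largest rises came mostly from runs of neighbouring genes. The alkaline phosphatase gene sll0654 rose 7.08-fold (log2 fold change 2.82 ± 0.17 SE, limma adjusted p = 5.45e-04). The extracellular nuclease gene sll0656 was not well above background in the wild type and was at least 3.50-fold higher in the ethylene-producing strain (limma adjusted p = 0.0022). The genes sll0679 to sll0683, which encode a phosphate-binding protein and a high-affinity phosphate transporter, rose by between 1.33 (sll0679) and 2.07 (sll0680) on the log2 scale. sll0680, a phosphate-binding protein gene, went from -0.28 ± 0.10 (SD, n = 2) to 1.79 ± 0.18. The adjacent genes sll1077 to sll1081 rose by 2.10 ± 0.28 SE (sll1077), 2.77 ± 0.26 (sll1078), 2.00 ± 0.21 (sll1079), 2.23 ± 0.22 (sll1080) and 2.05 ± 0.28 (sll1081) on the log2 scale. sll1077 is known as a guanidine hydrolase, and sll1078 and sll1079 encode nickel-handling accessory proteins. The 3 remaining genes were sll1471, the phycobilisome linker gene cpcG2 (4.00-fold, limma adjusted p = 0.0114), sll0450, a nitric oxide reductase gene (3.58-fold, adjusted p = 0.0278), and sll1314 (2.37-fold, adjusted p = 0.0035). The calls of sll1077 and sll0450 ended without wild-type replicate 1, that of sll0450 also without wild-type replicate 2, and those of sll1081 and sll1471 without ethylene-producing replicate 2.

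After slr1214, the largest falls were mostly of pSYSA genes, given with that plasmid. Among chromosomal genes, isiA (sll0247) fell 3.87-fold, from 3.97 ± 0.47 (SD, n = 2) to 2.02 ± 0.07 (limma adjusted p = 0.0083), a call that ended when either ethylene-producing array was left out. sll1240 fell 3.70-fold (log2 fold change -1.89 ± 0.11 SE), slr0534, annotated as a transglycosylase gene, 3.59-fold (-1.84 ± 0.11 SE), slr2043, a zinc-binding transport protein gene, 3.32-fold (-1.73 ± 0.12 SE), and ssl1326 3.20-fold (-1.68 ± 0.13 SE). All 4 had limma adjusted p-values of 0.0016 or less.

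Most photosystem I, phycobilisome and ribosomal protein genes had higher signal in the ethylene-producing strain. All 12 photosystem I genes tested had higher signal (median log2 fold change 0.48); 4 rose over all features and 12 when adjusted over the list alone, among them psaB (slr1835, 0.63 ± 0.11 SE), psaM (smr0005, 0.55 ± 0.10 SE), psaK2 (sll0629, 0.57 ± 0.12 SE) and psaK1 (ssr0390, 0.53 ± 0.11 SE). Of 15 phycobilisome genes 14 had higher signal (median 0.45); 6 rose, and 11 when adjusted over the list alone, including the linker genes cpcG2 (sll1471), cpcC2 (sll1579, 0.85 ± 0.11 SE), cpcC1 (sll1580, 0.85 ± 0.11 SE) and cpcD (ssl3093, 0.83 ± 0.11 SE). Of 38 ribosomal protein genes 37 had higher signal (median 0.32), or 35 to 37 across the other scalings; 3 rose, and 7 when adjusted over the list alone: sll1746 (0.77 ± 0.13 SE), sll1745 (0.65 ± 0.13 SE) and sll1800 (0.66 ± 0.13 SE) passed over all features. The calls of psaM, psaK2 and psaK1 ended with median centring (limma adjusted p = 0.0518, 0.0518 and 0.0573) and without the dim filter (0.0536, 0.0631 and 0.0656), that of psaK1 also with the median over probes (0.0536). Those of sll1745 and sll1800 ended without the dim filter (0.0611 and 0.0634), that of sll1800 also with the median over probes (0.0527). The calls of all 4 photosystem I genes, of cpcC1 and cpcC2 and of the 3 ribosomal protein genes ended when any 1 array was left out, and that of cpcD in every case but wild-type replicate 2. Limma's camera with its preset correlation called all 3 lists upward, with adjusted p-values of 2.24e-06 for photosystem I, 2.24e-06 for the phycobilisome and 1.85e-06 for ribosomal proteins. With an estimated correlation camera called none of the 3 (adjusted p = 0.702 each). Neither did fry's directional test (adjusted p = 0.0651, 0.0651 and 0.145, in the same order). At the preset correlation all 3 stayed called under every change of processing. Photosystem II had no called gene among 25 (median 0.15, camera adjusted p = 0.127), and sll0427, the gene of an extrinsic subunit, had the smallest p (0.52 ± 0.13 SE). Neither the 8 genes of the cytochrome b6f complex and electron carriers (median 0.17), the 9 of ATP synthase (median 0.30) nor the 16 of NDH-1 and respiration (median 0.15) held a called gene by either adjustment. The 2 phycobilisome degradation genes, ssl0452 (-0.32 ± 0.16 SE) and ssl0453 (-0.10 ± 0.17 SE), did not pass.

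**Figure D2:**
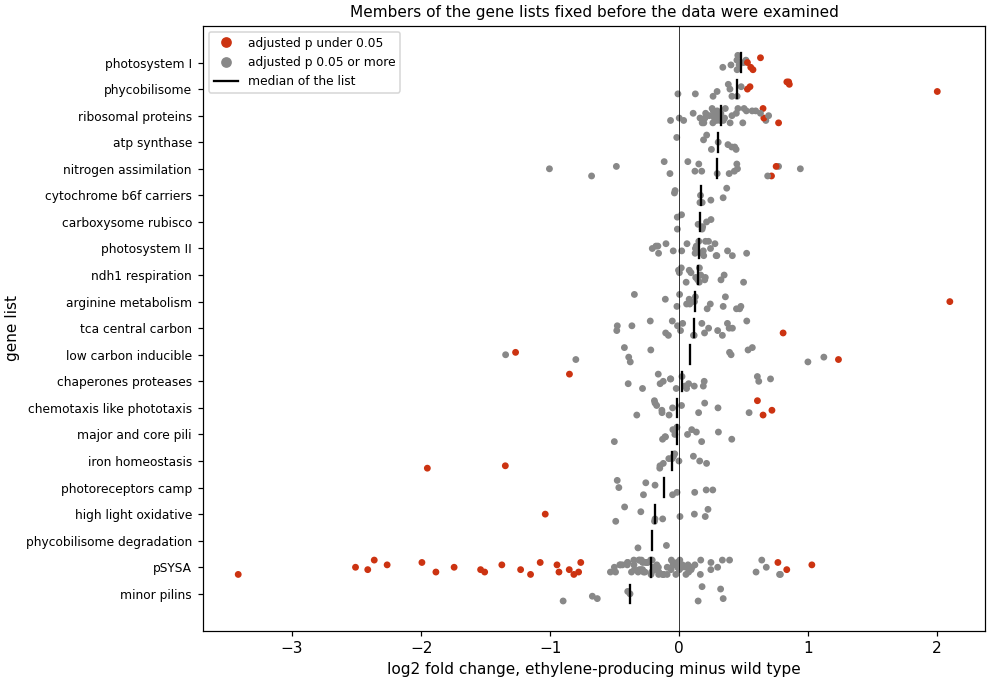
Log2 fold change, ethylene-producing minus wild type (x axis), of every tested gene in each list except the ethylene locus (y axis), dim genes at their measured value, with genes past the adjusted threshold in red, others in grey and the list median as a black bar. All 12 photosystem I genes lie above 0, with a median of 0.48, and the pSYSA list has a long lower tail.

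Carbon, nitrogen and stress lists held few called members, and camera called none of the lists with all arrays. Without wild-type replicate 1 it called nitrogen assimilation upward, and without replicate 2 iron homeostasis downward. Fry's directional test called central carbon (adjusted p = 0.0233). Its mixed test called all of these lists but iron homeostasis and carboxysome and Rubisco (adjusted p = 0.0131 to 0.0492). In the low-carbon inducible list (14 genes, median 0.09) sll0218 of the flv4-flv2 operon rose 2.35-fold and slr0044, of the bicarbonate transporter operon cmp, fell 2.41-fold. When adjusted over the list alone 5 rose and 2 fell. Beside sll0218, sll0217 and sll0219 had log2 fold changes of 1.00 ± 0.27 SE and 1.12 ± 0.26 SE. Beside slr0044, slr0040 to slr0043 had -1.35 to -0.38, and none of these neighbours passed over all features. The list's median thus hides opposed runs of genes. Of 19 nitrogen assimilation genes 2 rose, sll1689 (the sigma factor gene sigE, 0.75 ± 0.11 SE) and sll0108 (the ammonium transporter gene amt1, 0.72 ± 0.12 SE), and 4 rose when adjusted over the list alone. Of 17 arginine metabolism genes only sll1077 rose over all features, and 2 when adjusted over the list alone; its product is now known to act on guanidine. Of 22 central carbon genes 1 rose, the glyceraldehyde-3-phosphate dehydrogenase gene slr0884 (0.81 ± 0.12 SE), and 1 rose and 2 fell when adjusted over the list alone. None of the 8 carboxysome and Rubisco genes passed by either adjustment (median 0.16). Among 19 chaperone and protease genes the protease gene htrA (slr1204) fell by 0.85 on the log2 scale, and 3 rose and 1 fell when adjusted over the list alone; the list's median was 0.02, its mean 0.03 and camera's direction down (adjusted p = 0.994). Of 11 high light and oxidative stress genes 1 fell by both adjustments, hliB (ssr2595, -1.04 ± 0.14 SE). Of 13 iron genes 2 fell by both adjustments, isiA (sll0247) and the flavodoxin gene isiB (sll0248, -1.35 ± 0.27 SE, limma adjusted p = 0.0471). The antisense RNA of isiA, IsrR, rose 2.67-fold (limma adjusted p = 0.0353), a call that ended when either ethylene-producing array was left out. The call of isiB ended without the dim filter (limma adjusted p = 0.0606). Those of sigE and amt1 ended when any 1 array was left out, those of isiB and hliB without any array but wild-type replicate 2, that of slr0884 without any but wild-type replicate 1, and that of htrA without either ethylene-producing array. IsrR and Yfr1 were the 2 regulatory RNAs matched by name, and Yfr1 did not pass (0.04 ± 0.12 SE).

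Transcripts of the plasmid pSYSA, which carries CRISPR-Cas systems, were lower mainly in a block of tags. Of 96 pSYSA genes tested 20 fell and 3 rose, and 29 fell and 8 rose when adjusted over the list alone, with a median log2 fold change of -0.22, or -0.21 with genes not well above background set at their bound. Limma's camera called the list downward with its preset correlation (adjusted p = 1.49e-08), and fry's directional test called it too (adjusted p = 0.0281). With an estimated correlation camera did not call it (adjusted p = 0.280). The falls included slr7096 (5.69-fold), slr7081 (5.33-fold), slr7099 (5.15-fold), slr7097 (4.80-fold), slr7098 (3.98-fold), slr7101 (3.69-fold) and slr7095 (2.91-fold), all with limma adjusted p-values of 0.0011 or less. slr7100 and slr7082 were not well above background in the ethylene-producing strain and were at least 6.69-fold and at least 2.01-fold lower there (limma adjusted p = 2.13e-04 and 0.0099), the second call ending without ethylene-producing replicate 2. From slr7081 to slr7102, limits chosen after the values were seen, 12 of 16 genes of the slr and ssr series fell, whereas none of 9 genes or antisense features of the other strand fell and 1 rose. Other-strand genes fell just outside: from sll7070 to slr7102, 15 of 22 genes of the slr and ssr series and 3 of 15 features of the other strand fell. The genes named next were also chosen after their values were seen. Away from that stretch, at lower tags, sll7002 (-0.82 ± 0.11 SE) and slr7012 (-0.78 ± 0.13 SE) fell too. The 3 other-strand falls within the stretch were sll7077 (-1.37 ± 0.12 SE), sll7078 (-1.08 ± 0.17 SE) and sll7070 (-0.85 ± 0.12 SE), and the list's 3 rises were sll7089 (0.83 ± 0.12 SE), sll7064 (1.03 ± 0.14 SE) and sll7065 (0.77 ± 0.13 SE). Of these 6 calls only that of sll7077 held without each array. In the ethylene-producing strain sll7077 and sll7078 had mean signals of -5.18 and -5.37. Both lay under the lowest signal of a probe well above background there (-4.78 on replicate 1, -5.12 on replicate 2). The sizes of these 2 falls thus rest on signal near background. The pSYSM, pSYSX and pSYSG lists had no tested member.

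**Figure D3:**
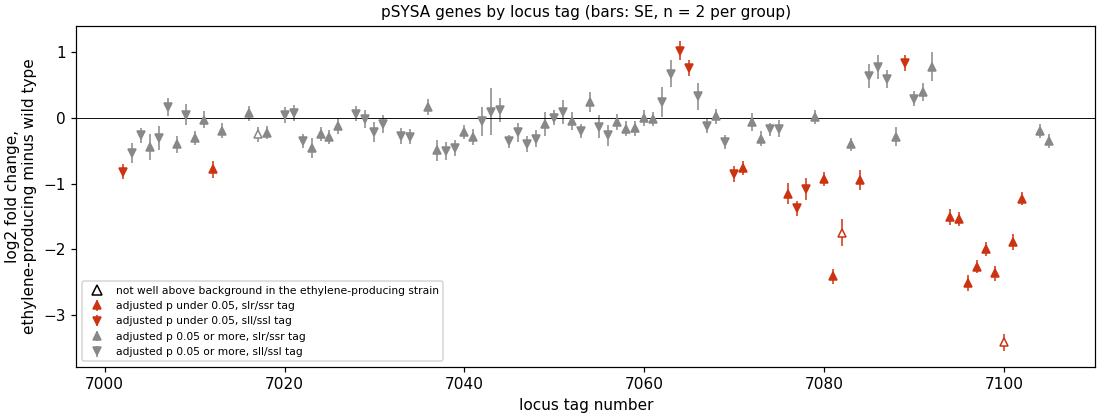
Log2 fold change, ethylene-producing minus wild type (y axis, bars SE, n = 2 per group), of the 96 tested pSYSA genes by locus tag number (x axis). Upward triangles are slr or ssr tags, downward triangles sll or ssl tags, red marks genes past the adjusted threshold and open symbols genes not well above background in the ethylene-producing strain; the lower genes lie mostly between slr7076 and slr7102.

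Of 2700 non-coding features tested, 55 were higher and 144 lower (limma, adjusted p under 0.05). Antisense features gave 18 higher and 37 lower of 1410, untranslated regions 18 and 7 of 684, other non-coding RNAs 19 and 30 of 515, and spacer or leader features 0 and 70 of 91. The features named as spacers fall into 3 series by a suffix that the files do not define, each measured by 1 probe. Spacer is the usual name for a part of a CRISPR array, but the files do not place these features on a plasmid. With suffix 0, 21 of 49 spacers on the array were tested, of which 4 fell, and the median was -0.07. The 4 falls were those with the highest numbers tested, Spacer47-0-x, Spacer51-0-x, Spacer52-0-x and Spacer53-0-x. With suffix 1, 35 of 37 fell, and the median with dim spacers at their bound was -1.92; with suffix 2, 30 of 30 fell, with a median of -2.27. Spacers of suffix 1 numbered below 20 had a median of -1.41 and those from 20 upward -2.36 at their bound; for suffix 2 these were -1.94 and -2.55. The 5 falls with the smallest p were all spacers not well above background in the ethylene-producing strain: Spacer38-2-x was at least 19.7-fold lower, Spacer35-1-x at least 11.3-fold, Spacer45-1-x at least 9.07-fold, Spacer47-0-x at least 8.88-fold and Spacer52-0-x at least 8.57-fold, each with limma adjusted p = 1.28e-04. Counted together, 89 pSYSA genes and spacers fell, and 67 of them, or 75.3%, were still well above background on both ethylene-producing arrays. The 5 rises with the smallest p were the untranslated regions of sll0680 (2.03 ± 0.13 SE) and sll0681 (1.92 ± 0.15 SE) and the RNAs NC-174 (1.41 ± 0.13 SE), NC-171 (1.38 ± 0.13 SE) and NC-230 (1.34 ± 0.14 SE), the last 2 of which share a probe sequence. Outside these kinds, 59 of 1768 internal transcripts were higher and 40 lower, and none of 31 stable RNAs passed by limma, with 0 also at an unadjusted p under 0.05.

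**Figure D4:**
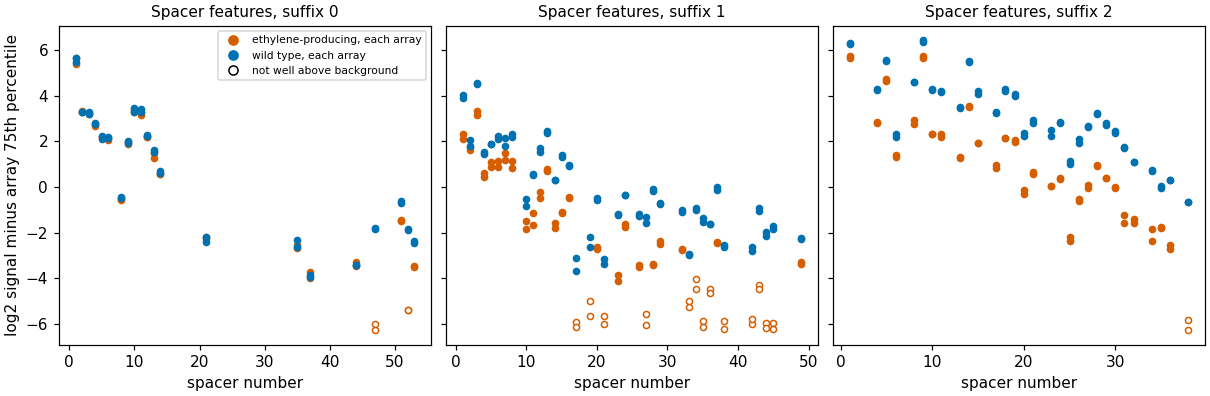
Signal of each tested spacer on each array, as log2 processed signal minus the array's 75th percentile (y axis), by spacer number (x axis) in one panel per suffix. Orange points are ethylene-producing arrays, blue points wild-type arrays (n = 2 each) and open points spacers not well above background in that group. The suffix 0 spacers have a median log2 fold change of -0.07, with 4 falls at the highest numbers, while those of suffix 2 are lower (median -2.27).

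Leaving out 1 array lowered the count of called genes from 188 to 42 to 121, and normexp background correction lowered that of genes changed at least 2-fold from 63 to 32. All 4 arrays lay on 1 slide, with the wild type at positions 1 and 2 and the ethylene-producing strain at 3 and 4, and only that strain's medium is described with antibiotics, so position, vector, antibiotics and ethylene cannot be told apart.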

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

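No test in this part was chosen after the results were seen, but some of the genes it covers were. Of the 30 genes with the largest changes, 24 kept their direction and their call in all 14 settings that could measure them, and all 10 non-coding features named did so too. Calls were lost for 1 gene under a change of processing, sll1081 with the median over probes (1.90, adjusted p = 0.0567, against 0.0149), and for 6 genes without 1 array. Among the other 79 genes and RNAs named from lists, 44 kept their side of the threshold under every change of processing and 54 without each array. Of 31 genes and RNAs named after their values were seen, 21 kept their side under every change of processing and 10 without each array. Of the 188 called genes, none changed sign in any setting, but several settings could not have turned a sign. The filters, the intensity trend and the replicate block leave the fold changes as they are. Leaving out 1 array cannot turn a sign where the groups' arrays do not overlap, a condition for choosing the 30 genes.

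Where the count of 188 called genes (90 higher, 98 lower) moved by over 1.5 times, the values were as follows, and the causes were not tested unless stated. With normexp background correction 288 genes were called, 174 higher; with normexp and quantile normalization 150 were lower, and 153 were lower in the value table. Without the dim filter 57 were higher. Genes changed at least 2-fold numbered 32 with normexp, 33 with normexp and quantile normalization and 32 in the value table. At an adjusted p under 0.1, 469 genes were called, 255 higher and 214 lower; at 0.01, 48, of which 15 higher and 33 lower. With fewer arrays 42 to 121 genes were called (70 without ethylene-producing replicate 1, 42 without replicate 2, 60 without wild-type replicate 1, 121 without replicate 2), 16 to 53 higher and 26 to 68 lower, and 79 to 132 non-coding features. Called genes of at least 2-fold then numbered 42 to 85.

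With the replicate number as a block, 565 genes (327 higher, 238 lower) and 450 non-coding features were called. Same-numbered arrays deviated together with a correlation of 0.272 over features, but with 2 pairs and no label that says so the numbers are not taken to pair the samples. Of the gene lists, 4 were called; 0 with an estimated correlation, 2 by fry directional (pSYSA and central carbon), 15 by fry mixed, and 4 to 7 without 1 array, the 7 without wild-type replicate 1, which added photosystem II, ATP synthase and nitrogen assimilation, all upward; without replicate 2 iron homeostasis was added, downward. Among the genes and RNAs named, signs turned for slr1213, at -0.0049 with median centring and -0.078 to 0.17 without 1 array, ssl0453, at -0.29 to 0.092 without 1 array, slr1667, at -1.40 to 1.02 without 1 array, and Yfr1-0-x, at -0.016 with median centring, -0.12 with quantile normalization, -0.022 with normexp and quantile normalization, -0.043 in the value table, and -0.079 to 0.15 without 1 array. List medians turned for chaperones (-0.031 with median centring, -0.011 with quantile normalization, -0.0034 with normexp and quantile normalization, -0.017 in the value table), for chemotaxis (0.0012 with normexp), for the major and core pili (8.74e-04 with normexp and quantile normalization) and for the ethylene locus (-0.0049 with median centring). A slide block was not run because 1 slide held all arrays. Signal over background limits the folds of dim features, which are bounds.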

Other observations

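All tests in this part were chosen after the results were seen, and the genes in this paragraph were picked after their values were seen. Besides slr2043, the neighbouring zinc transport genes slr2044 (log2 fold change -0.86 ± 0.11 SE) and slr2045 (-0.71 ± 0.11 SE) fell, as did the manganese transport genes sll1598 (-1.26 ± 0.19 SE), sll1599 (-1.32 ± 0.13 SE) and sll1600 (-1.14 ± 0.10 SE). slr1215, next to slr1214, fell by 0.99 on the log2 scale. Around sll1471 the genes sll1472 (1.13 ± 0.16 SE) and sll1473 (0.70 ± 0.14 SE) rose, and so did the adjacent genes slr1852 to slr1855 (0.90 to 1.02). Few of these calls held throughout: those of slr2044, slr2045 and sll1473 ended without each array, those of slr1852 to slr1855 without any array but ethylene-producing replicate 1, that of sll1598 without either ethylene-producing array, that of sll1599 without ethylene-producing replicate 2, and those of slr1215 and sll1472 without that array or wild-type replicate 1. Without the dim filter the calls of slr1854 and slr1855 ended (limma adjusted p = 0.0504 and 0.0544). That of slr2045 also ended with normexp (-0.17, adjusted p = 0.194), normexp and quantile normalization (0.104), the value table (0.0875) and the median over probes (0.0631). That of sll1473 also ended with normexp (0.36, adjusted p = 0.0521), normexp and quantile normalization (0.107), the value table (0.135), no dim filter (0.0644), the median over probes (0.120) and an intensity trend (0.0555). The sulfate transport genes slr1452 to slr1455 did not pass, with log2 fold changes of -1.87 ± 0.64 SE, -1.73 ± 0.61, -1.55 ± 0.68 and -1.16 ± 0.42; replicate 1 was above replicate 2 for all 4 in both groups. slr1667, a cAMP-dependent gene linked to motility, differed between replicates 1 and 2 by 1.75 in the ethylene-producing strain and 2.42 in the wild type, against -0.19 ± 0.88 SE between the groups. A split of the arrays by replicate number called 0 of 7939 features with limma, and 106 at an unadjusted p under 0.05. Differences between the strains count as spread in this split, so it cannot show that the replicates are alike.

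The lower signal of pSYSA genes and of the spacers, which the files place on no plasmid, was set against changes in DNA. Fewer copies of the whole plasmid would lower all its genes. Of the 96 genes 69 had a negative and 27 a positive log2 fold change, with a median of -0.22 (95% bootstrap interval -0.29 to -0.14). Across the other scalings this median was -0.27 to -0.10. A loss of copies as large as the falls of the called genes is thus argued against, but a small loss stays open. The intervals in this paragraph come from resampling features, not arrays, and treat neighbouring genes as separate. They do not measure the spread between samples. Loss of the stretch from slr7081 to slr7102 would lower both strands, but the median of the 9 opposite-strand genes and antisense features was 0.30 (-0.16 to 0.64), and slr7101-as1 stood at 0.21 ± 0.13 SE where slr7101 fell by 1.89; the lowest of the 9 was slr7098-as2 (-0.57 ± 0.19 SE). Those limits leave out, among others, the falls of sll7070, sll7077 and sll7078. From sll7070 to slr7102 the median of 15 opposite-strand features was -0.047 (-0.57 to 0.30). Loss of all of this longer stretch is argued against too, since it contains the shorter one, where sll7085, sll7086, sll7087 and sll7089 stood at 0.64, 0.78, 0.60 and 0.83 and slr7091 and slr7092 at 0.39 and 0.78. Loss of shorter pieces to either side of these genes was not tested and stays open. Loss of single spacers stays open: of 16 spacers at background only in the ethylene-producing strain, 5, or 31.2%, were lower than their nearest measured neighbours by more than 1 on the log2 scale even at their bound, Spacer47-0-x and Spacer52-0-x among them. Spacers at background were skipped as neighbours. Of the 5, Spacer35-1-x lay between Spacer34-1-x and Spacer36-1-x, both at background. Spacer43-1-x likewise lay between Spacer42-1-x and Spacer44-1-x, both at background, so neither is shown to fall alone. A hypothesis that stays untested is that transcription or processing of the pSYSA and spacer RNAs differs between the strains, which may be due to ethylene, the vector or the strains' separate histories.

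The rise of sll1077 to sll1081 was not carried by a single probe or spot: 40 of 40 spots, or 100%, were higher in the ethylene-producing strain. The genes were picked for their rise in these same spots, so the count is no separate support for it. As the ethylene-forming enzyme is known to release guanidine when it uses arginine, a candidate explanation is induction of these genes by guanidine. The next gene, sll1082, had a log2 fold change of 0.96 ± 0.27 SE (limma adjusted p = 0.0913), which leaves this open, and guanidine itself was not analysed here.

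The phosphate genes sll0654, sll0656 and sll0679 to sll0684 were higher on 64 of 64 spots, or 100%, so no single probe or spot carried the rise. These genes too were picked from the same spots. The call of sll0684 ended without ethylene-producing replicate 2. The second phosphate transporter genes slr1247 to slr1250 had a median log2 fold change of 0.43 (range 0.19 to 1.12), a direction consistent with a phosphate limitation response. That support is weak, since only slr1247 passed (limma adjusted p = 0.0280), and its call ended without either ethylene-producing array or wild-type replicate 1. Its wild-type signals (-5.67 and -5.26) also lay under the lowest signal of a probe well above background on those arrays (-5.23 and -4.91). The value of 1.12 for slr1247 thus rests on signal near background. Whether the cultures differed in phosphate or the strain in its regulation stays open, since strain and culture are confounded.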
